A study of Mus musculus with 2 samples.

How the data were processed

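Chromatin from limbs of C57BL/6 mouse embryos at embryonic day 14.5 was immunoprecipitated with an antibody to H3K9me3, the trimethylated form of a lysine in the tail of histone H3 that marks heterochromatin, and sequenced (ChIP-seq). The 2 samples formed 1 group of 2 biological replicates. Per the labels, replicate 1 came from 24 embryos and replicate 2 from 34, each a pool of male and female embryos with 3 technical replicates. No second tissue, stage or mark was analysed here, so the comparisons were between the replicates and between regions of the genome.

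The authors deposited 4 peak lists on the mouse build mm10: 1 for each replicate, 1 called on both replicates together (the pooled list), and a subset of the pooled list that the authors named replicated peaks. Each peak carries the authors' fold enrichment, a linear ratio, and the authors' −log10 p and −log10 q values. The peak caller, the aligner and the rule that made the replicated subset are not given in the sources used here. Per the file headers of the accompanying notes, replicate 1's list and the pooled list were each derived from alignments and 2 further files whose role is not stated, and replicate 2's list from alignments and 1 such file, so the replicates may not have been processed alike. The weakest deposited peaks had a −log10 p of 2.01 in replicate 1 and 2.03 in replicate 2. Fold and −log10 values were used to describe, rank or filter peaks within their own list, to correlate the folds of touching peaks of the replicates, to set the replicates' folds beside those of the highest peaks and, in the closing section, to model the reads behind them. The files give no read counts, so the depth is unknown, and no interval that needs it is given.

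Positions were compared with the GRCm38.p6 assembly, whose chromosome lengths match mm10, and with GENCODE release M21. Peaks on the 21 assembled chromosomes (19 autosomes, X and Y) entered all placement and gene tests, and peaks on unplaced contigs were counted apart. Gene spans ran from the first to the last base of all transcripts. Overlap meant at least 1 shared base unless another rule is named. Random placements kept each peak's width and chromosome and avoided assembly gaps (bedtools 2.31.1, 1000 placements, 100 for repeat content). Repeats were the soft-masked bases of the assembly. Context was taken at the peak midpoint, in the order promoter (within 1 kb of a protein-coding transcription start site), exon, intron, outside. Exons and introns were those of protein-coding genes. Here and below, outside genes means outside protein-coding genes, so peaks in other annotated genes counted as outside.

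Before the data were examined, 16 gene lists were fixed: imprinted, zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, defensin, keratin, cytochrome P450, germline, limb patterning and skeletal, limb muscle, neural, liver, blood and immune, pluripotency, and housekeeping genes. The number of members with a replicated peak was set against 10000 random lists matched on gene span in 20 bins (two-sided permutation test; the smallest p that it can give is 0.0002), drawn with replacement from genes outside the list, with Benjamini-Hochberg adjustment over the 16 lists. For zinc finger genes, cover of the last exon was compared with cover of the rest of the gene by an exact two-sided sign test. Genes named in the text were chosen by a rule written before the data were examined: up to 4 members per list with the largest share of their span in replicated peaks (the list's opening 2 members where none had a peak), the 10 protein-coding genes with the most covered bases, the genes at the 10 peaks of highest fold, 12 control genes, and the 5 domains (peaks joined over gaps of up to 10 kb) with the most covered bases. Among the named genes, Zfp42 and Peg3 belong to more than 1 list, as do some members that are not named.

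Alternatives were stricter q limits (−log10 q of at least 2 or 5), other overlap rules, other promoter and gene windows, the pooled list, each replicate's own list, rotations of the peaks along their chromosomes, which keep clusters of peaks and genes together, and Fisher's exact test without span matching. The setting with 1 gene per cluster (members within 500 kb of one another) was planned for last exons and added for gene lists after the data were seen. Among gene lists it was run on imprinted, zinc finger, vomeronasal receptor and germline genes, which had passed, and its p-values were adjusted over these lists alone. Settings without zinc finger and protocadherin genes (leaving out the peaks that touch them, or both those peaks and the random placements that touch them) were also added after the data were seen. Genes that lie in clusters are not independent of one another, so the span-matched p-values can be too small for clustered families, and the rotations bear on that. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

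The gene list test, the overlap test and the sign test were checked on simulated data with and without a planted effect, and the count of bases covered was checked on simulated intervals. The simulated genes were independent of one another, so these checks do not bear on the p-values of clustered families.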

Results

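H3K9me3 was mapped in the developing limb of the mouse at embryonic day 14.5, in 2 biological replicates of 1 group. Replicate 1's list held 32634 peaks over 9.97 Mb and replicate 2's 12410 peaks over 3.91 Mb, a ratio of 2.63 in number and 2.55 in covered bases. Peaks were narrow in both, with median widths of 245 and 247 bases and lower quartiles of 206 and 207. The median deposited folds were 3.15 and 3.33. A −log10 q of at least 2 was reached by 20.5% of replicate 1's peaks and 16.4% of replicate 2's. Most peaks in these lists thus lay under that limit. How far the widths and the covered bases depend on the peak calling, rather than on the mark, was not tested. The pooled list held 34874 peaks. The replicated set, to which the values below refer unless a replicate is named, held 13617 peaks with a median width of 390 bases and covered 0.247% of the sequenced genome. Values given for each replicate come from its own list, and with 2 replicates they are given as a pair in place of an SD.

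The question of where in the genome the limb carried this mark was addressed with the 16 gene lists. Imprinted genes, clustered protocadherin genes, zinc finger genes, germline genes and vomeronasal receptor genes carried replicated peaks in more members than span-matched random lists. The vomeronasal call was lost when rotations kept the clusters of genes and peaks together (adjusted permutation p = 0.10; 0.00053 to 1 over the 9 alternatives, Fisher's exact test included). Limb patterning, limb muscle, neural, liver, blood and housekeeping genes did not pass the span-matched test. Over all protein-coding genes, 2664 of 21911 (12.2%) had a replicated peak in their span.

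**Figure D1:**
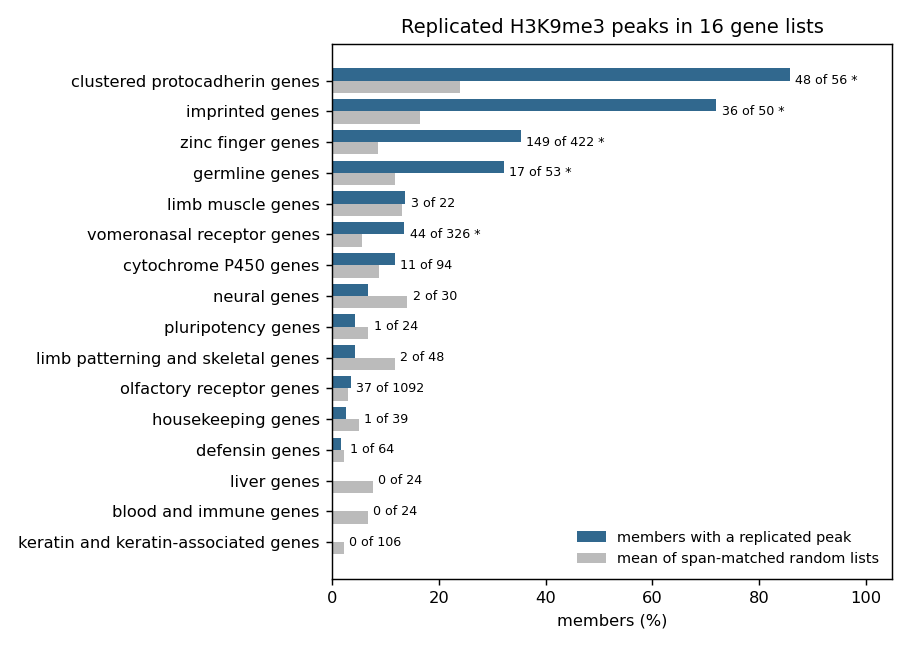
Share of the members of each gene list with a replicated H3K9me3 peak in the gene span (blue bars, in %) and the mean share in 10000 span-matched random lists (grey bars). The numbers are members with a peak of all members, and an asterisk marks lists with an adjusted p under 0.05. Clustered protocadherin genes (48 of 56) and imprinted genes (36 of 50) stand highest.

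Imprinted genes, which are expressed from the maternal or the paternal copy alone, carried the mark in 36 of 50 members, against 8.18 in random lists (ratio 4.40, adjusted permutation p = 0.0008). With replicate 1's own list 41 members were marked against 14.8 (ratio 2.76), and with replicate 2's 33 against 7.38 (ratio 4.47). Cdkn1c, an inhibitor of cyclin-dependent kinases (chromosome 7, 143458339 to 143461050), was covered over 74.7% of its span, 1679 bases in replicate 1 and 1495 in replicate 2. Nnat, which lies within the span of Blcap on chromosome 2, was covered over 73.4%, Nap1l5 on chromosome 6 over 65.5%, and the non-coding Peg13 on chromosome 15 over 35.9%. The control genes Peg3 (3.70 kb in 3 peaks), Mest (4.06 kb in 2 peaks) and Snrpn (2.23 kb in 4 peaks) were covered in both replicates. H19 had no replicated peak in its span, but 660 covered bases lay within 2.5 kb of its transcription start site. Within that window of the start site, 22 of the 50 members were marked, against 1.06 in random lists (adjusted permutation p = 0.0008; 6.1e-24 to 0.011 over the 9 alternatives, permutation and Fisher's exact tests).

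Germline genes, which act in meiosis and in the defence against transposons in germ cells, carried a replicated peak in 17 of 53 members, against 6.21 in random lists (ratio 2.74, adjusted permutation p = 0.0013). With replicate 1's own list the count was 21 against 11.8 (ratio 1.78), and with replicate 2's 16 against 5.61 (ratio 2.85). Within 2.5 kb of the start site 12 members were marked, against 1.08 in random lists (adjusted permutation p = 0.0008). Dazl, a germ cell RNA-binding protein on chromosome 17, had a peak of fold 6.30 in its span and 1430 covered bases within 2.5 kb of its start site. Taf7l on the X chromosome (1.02 kb), Meioc on chromosome 11 (1.09 kb) and Spo11, the enzyme that makes meiotic DNA breaks (chromosome 2, 0.30 kb), completed the members with the largest covered share. Spo11 had no peak in replicate 2's own list. Asking for at least 1 kb of cover left 2 members, against 1.49 in random lists (adjusted permutation p = 1; 0.0003 to 1 over the 9 alternatives, permutation and Fisher's exact tests).

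Zinc finger genes, many of which encode DNA-binding repressors of retrotransposons, carried replicated peaks in 149 of 422 members, against 35.9 in random lists (ratio 4.16, adjusted permutation p = 0.0008). Replicate 1's own list gave 186 members against 70.4 (ratio 2.64) and replicate 2's 154 against 32.2 (ratio 4.78). Zfp110 on chromosome 7 was covered over 88.5% of its span, 13.3 kb in replicate 1 and 11.8 kb in replicate 2. Zfp873 on chromosome 10 was covered over 86.1%, Zfp68 on chromosome 5 over 79.7% and Zfp146 on chromosome 7 over 78.2%. At least 1 kb was covered in 95 members, against 8.16 in random lists (ratio 11.6, adjusted permutation p = 0.0011; 1e-34 to 0.011 over the 9 alternatives, permutation and Fisher's exact tests).

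Within zinc finger genes the last exon, which in most of these genes encodes the zinc finger array, was more often the more covered part. In the 149 genes with a peak, the last exon was covered over a median 33.1% of its bases and the rest of the gene over 3.16%. The medians were 19.4% and 2.35% in 185 genes with a peak in replicate 1's own list. In 154 genes with a peak in replicate 2's own list they were 14.9% and 1.45%. Replicated peaks touched the last exon in 113 of the 149 genes. The last exon was the more covered part in 107 genes and the less covered part in 42 (exact two-sided sign test, p = 1e-07). Last exons made up 7.99% of the length of these genes and 40.6% of their covered bases. These shares were of all bases, repeats included. The repeat content of last exons was not compared with that of the rest, so its part in the difference was not tested. The last exons of Zfp146 (chromosome 7, 30161269 to 30163228), Zfp873 (chromosome 10, 82059517 to 82061581) and Zfp180 (chromosome 7, 24104405 to 24107713) were covered over 100% of their bases, while the rest of the gene was covered over 71.7%, 84.1% and 19.6%. With 1 gene per cluster, 46 of 73 last exons were the more covered part (exact sign test, p = 0.034).

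**Figure D2:**
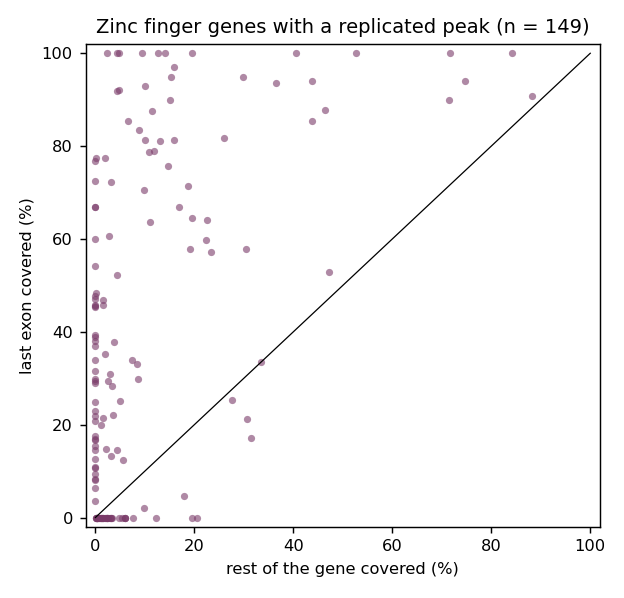
Each point is 1 of 149 zinc finger genes with a replicated peak, placed by the share of its last exon (vertical axis, in %) and of the rest of its span (horizontal axis, in %) that replicated peaks covered. The line marks equal cover, and 107 genes lie above it.

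The clustered protocadherin genes, neural cell adhesion molecules encoded in a single cluster on chromosome 18, carried replicated peaks in 48 of 56 members, against 13.4 in random lists (ratio 3.59, adjusted permutation p = 0.0008). The ratio was 2.34 with replicate 1's own list and 3.65 with replicate 2's. Their spans overlap, so the members are not independent, and rotations of the peaks, which keep the cluster whole, gave an adjusted permutation p of 0.016 (6.8e-35 to 0.016 over the 8 alternatives, Fisher's exact test included). The domain with the most covered bases in the genome lay here, over the gamma genes (chromosome 18, 37637330 to 37777817), with 74 peaks over 98.4 kb, 89.8 kb in replicate 1 and 74.9 kb in replicate 2. A second domain over the beta genes from Pcdhb15 to Pcdhb22 (37473286 to 37539211) held 42 peaks over 23.7 kb, 23.3 kb in replicate 1 and 9.95 kb in replicate 2. Pcdhga2 was covered over 51.9% of its span, Pcdhb20 over 56.9%, Pcdhb19 over 54.9% and Pcdhb22 over 54.2%. The 10 protein-coding genes with the most covered bases all lay in this cluster: the annotated genes Gm42416, Gm37013 and Gm37388, which span most of it and held 152 to 155 kb each, and Pcdhga1 to Pcdhga5, Pcdhgb1 and Pcdhgb2 with up to 92.4 kb each.

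**Figure D3:**
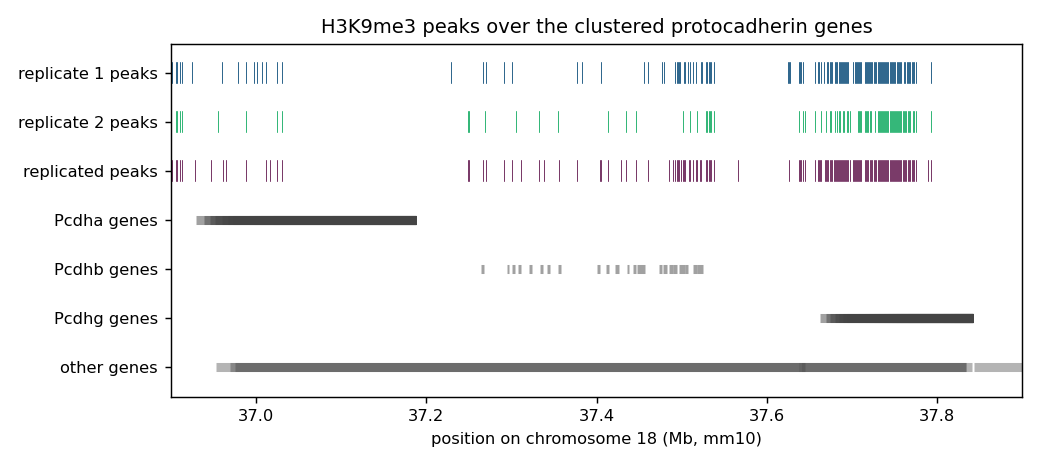
Peaks of replicate 1, replicate 2 and the replicated set (coloured marks, drawn to scale) over the clustered protocadherin genes on chromosome 18, with gene spans below as grey bars and the position in Mb on the horizontal axis. The domain over the gamma genes holds 74 replicated peaks over 98.4 kb and the domain over beta genes 42 over 23.7 kb.

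Vomeronasal receptor genes, which encode pheromone receptors, carried a peak in 44 of 326 members, against 18.3 in random lists (ratio 2.40, adjusted permutation p = 0.0008), with Vmn1r66, Vmn1r75, Vmn1r84 and Vmn1r43 covered over 16.8% to 7.76% of their spans. Vmn1r66 had no peak in replicate 2's own list. This call was lost in rotations of the peaks (ratio 1.75), with 1 gene per cluster and in Fisher's exact test, and among peaks with a −log10 q of at least 5 the ratio was 0.956. Olfactory receptor genes carried a peak in 37 of 1092 members, against 31.0 (ratio 1.19, adjusted permutation p = 0.50); Olfr631, Olfr137, Olfr348 and Olfr398 had the largest covered shares, 34.8% to 11.1%, and Olfr631 had no peak in replicate 2's own list. Their ratio was 1.58 with replicate 1's own list (102 members, adjusted permutation p = 0.00064) and 0.921 with replicate 2's (29 members, adjusted permutation p = 0.98), so the excess passed the test in replicate 1's list and not in replicate 2's; the difference itself was not tested. Asking for at least 1 kb of cover reversed it, with 2 members against 10.5 in random lists (ratio 0.191, adjusted permutation p = 0.013; 9.2e-25 to 1 over the 8 alternatives, Fisher's exact test included). Cytochrome P450 genes had 11 of 94 members with a peak (ratio 1.33, adjusted permutation p = 0.53). The ratio was 1.55 with replicate 1's own list (25 members) and 0.928 with replicate 2's (7 members), and the pooled list passed the test (ratio 1.59, adjusted permutation p = 0.039; 0.039 to 1 over the 8 alternatives, Fisher's exact test included). Members with a peak included Cyp3a11, Cyp3a16, Cyp3a57 and Cyp2b9 with 1.35 to 0.798 kb; Cyp2b9 and the defensin gene Defb33 had no peak in replicate 2's own list. Defensin genes had 1 of 64 (Defb33, adjusted permutation p = 1), and keratin genes, Krt1 and Krt10 included, had 0 of 106 (adjusted permutation p = 0.47). Random lists held 1.45 defensin and 2.26 keratin members, and 0 keratin members gave an unadjusted permutation p of 0.21. A deficit could thus not pass this test in either list.

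Neither list of limb genes passed the test. Of 48 limb patterning and skeletal genes 2 had a peak, against 5.60 in random lists (ratio 0.357, adjusted permutation p = 0.21): Sox5, a chondrocyte transcription factor whose span reaches 954 kb (13 peaks, 6.22 kb), and Runx2, a regulator of bone formation (3 peaks, 1.77 kb). Sox9, Prrx1, Hoxd13 and Col2a1 had no replicated peak, although replicate 1's own list placed 631 bases in Prrx1 and 382 in Col2a1. With that list 9 limb patterning and skeletal genes had a peak (ratio 0.939, adjusted permutation p = 1; 0.10 to 1 over the 8 alternatives, Fisher's exact test included), and with replicate 2's 2 had one (ratio 0.387). Among 22 limb muscle genes, Ttn (12 peaks, 7.27 kb), Myh8 and Pax3 had peaks (3 genes, against 2.85, adjusted permutation p = 1). Neither Myh8 nor Pax3 had one in replicate 2's own list.

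No list for other tissues, pluripotency or housekeeping passed the test, and with replicate 1's own list the ratios of neural (1.10), pluripotency (1.32) and housekeeping genes (1.04) lay above 1. Neural genes had 2 of 30 members with a peak (adjusted permutation p = 0.50), namely Slc17a7, a vesicular glutamate transporter covered over 19.4% of its span, and Syt1. Liver genes had 0 of 24 (Alb and Afp included, adjusted permutation p = 0.50) and blood and immune genes 0 of 24 (Hba-a1 and Hba-a2 included, adjusted permutation p = 0.52). Pluripotency genes had 1 of 24, Zfp42, with 557 bases at its start site (adjusted permutation p = 1), and Pou5f1 had none. Housekeeping genes had 1 of 39, Eif4g2 (adjusted permutation p = 1), and Actb and Gapdh had none in the replicated set or in either replicate. Random lists held 1.83 liver, 1.58 blood, 1.62 pluripotency and 1.94 housekeeping members. Even 0 members gave an unadjusted permutation p of 0.27 for liver and 0.36 for blood genes. A deficit could thus not pass this test in lists with so few expected members.

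Among the 10 replicated peaks of the highest deposited fold were peaks at zinc finger and other transcription factor genes. The highest on an assembled chromosome (fold 10.5; 7.52 in replicate 1 and 9.85 in replicate 2) lay 7 bases from Tcfl5, a basic helix-loop-helix transcription factor gene, at chromosome 2, 180642715 to 180644761, and reached into its promoter. A peak over Zfp180 (chromosome 7, 24103750 to 24109034, fold 10.4; 11 in replicate 1 and 5.06 in replicate 2) spanned its last exon. The peak at Klf14, a transcription factor gene (chromosome 6, 30955489 to 30959103, fold 8.67; 7.54 and 9.31 in the replicates), covered 3056 exonic bases. Further peaks among the 10 highest lay in 2610008E11Rik (folds 8.50 and 8.50, the former with 9.16 in replicate 1 and 4.30 in replicate 2), in Pcdhg genes (8.50), in Zfp68 (8.35), 22306 bases from Vmn1r77 (8.64) and in Gm49692, a processed transcript on chromosome 12 (8.83). The highest of all (fold 11.0) lay on an unplaced contig of chromosome 4 with no annotated gene. Beside the protocadherin domains, the domains with the most covered bases lay over the Ugt1a genes, which encode glucuronidating enzymes (chromosome 1, 88203292 to 88258324, 20 peaks, 45.0 kb), over Gm10775 and Zfp369 (chromosome 13, 65244004 to 65307421, 37 peaks, 32.1 kb), and on chromosome 4 (3050145 to 3091124, 13 peaks, 24.1 kb) where no protein-coding gene is annotated.

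Exons held 4.91% of the replicated peaks by midpoint, against 3.3% ± 0.152 of random placements (SD over 1000 placements; ratio 1.49, adjusted permutation p = 0.0027). Introns held 31.4% against 36.1% ± 0.400, and sequence outside genes 61.0% against 57.9% ± 0.422 (both adjusted permutation p = 0.0027, from the smallest raw p that 1000 placements can give, 0.002). Promoters held 2.69%, as did random placements (adjusted permutation p = 1), but this call was not stable. With replicate 2's own list promoters were over-represented (ratio 1.17, adjusted permutation p = 0.0053), and without the peaks and placements that touch zinc finger or protocadherin genes they were under-represented (ratio 0.869, adjusted permutation p = 0.016; 0.0027 to 0.47 over the 7 alternatives). Leaving out the 663 peaks that touch zinc finger or protocadherin genes, and the placements that touch them, ended the excess in exons (3.12% against 3.21%, ratio 0.970, adjusted permutation p = 0.54; 0.0027 to 0.54 over the 7 alternatives). Among the 2156 peaks with a −log10 q of at least 5, promoters (5.33%, ratio 2.04) and exons (10.5%, ratio 3.26) were over-represented, and the excess outside genes turned into a deficit (51.1%, ratio 0.878). Soft-masked repeats made up 26.0% of peak bases, against 33.7% ± 0.305 of random placements (permutation p = 0.02, the smallest that 100 placements can give). Placements avoided assembly gaps alone, and loss of reads within repeats was not tested, so a low level of the mark in repeats is not shown.

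Chromosomes 7, 17 and 18 had the highest cover, 2.08, 1.97 and 1.59 times the genome's mean per Mb. Replicate 1 gave 1.96, 1.84 and 1.40 and replicate 2 gave 2.04, 1.92 and 1.63. The lowest autosome, chromosome 14, lay at 0.614. The X chromosome lay below every autosome at 0.168, with 121 peaks (0.267 in replicate 1 and 0.199 in replicate 2), and the Y chromosome held 6 peaks. Soft-masked repeats make up 96.3% of the Y, and the pools held female embryos too. The 6 peaks therefore cannot show a low level of the mark there. The distance of X from the lowest autosome was larger than the spread between the replicates. Chromosome 18's cover included the protocadherin domains of 98.4 and 23.7 kb. By number of peaks per Mb it reached 1.36 times the genome's mean, below the 1.38 of chromosome 13.

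**Figure D4:**
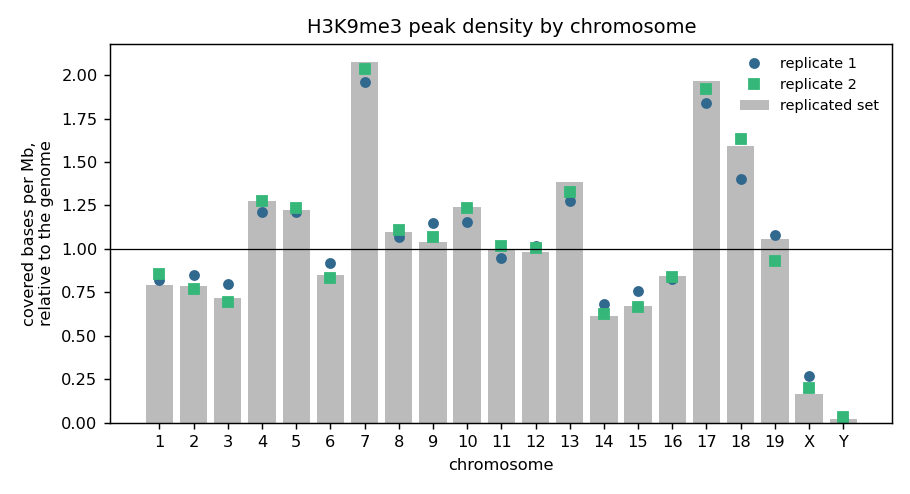
Bases covered by replicated peaks per Mb of sequenced chromosome, relative to the genome's mean (grey bars), with the values of replicate 1 (circles) and replicate 2 (squares). Chromosome 7 reaches 2.08 and the X chromosome 0.168.

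The replicates marked shared regions far more often than random placements did. Of replicate 1's 32381 peaks on assembled chromosomes, 5894 (18.2%) touched a peak of replicate 2, against 0.331% ± 0.0333 for random placements. Of replicate 2's 12177 peaks, 6063 (49.8%) touched one of replicate 1, against 0.881% ± 0.0872 (SD over 1000 placements; one-sided permutation p = 0.001 for both, the smallest that 1000 placements can give). The shorter list limits the share of replicate 1's peaks that can be touched; with lists of equal length the shares were 30% and 32.9%. Among peaks with a −log10 q of at least 5, 725 of 920 in replicate 1 (78.8%) and 303 of 313 in replicate 2 (96.8%) touched the other, unfiltered list. Of those under 1 the shares were 9.72% and 39.8%. With both lists held to at least 5, the shares were 22.7% (209 of 920) in replicate 1 and 71.2% (223 of 313) in replicate 2. Across the 5894 touching pairs, folds were related with a Pearson r of 0.352 on the log2 scale and a Spearman rho of 0.273; peaks are not independent replicates, and no p is given. For the authors' replicated peaks, a match meant that at least 0.5 of the length of either peak was shared. By that rule 77.7% were found in replicate 1's own list, 53.9% in replicate 2's, 41.0% in both and 9.38% in neither. With at least 1 shared base, 41.6% were in both and 9.04% in neither.

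**Figure D5:**
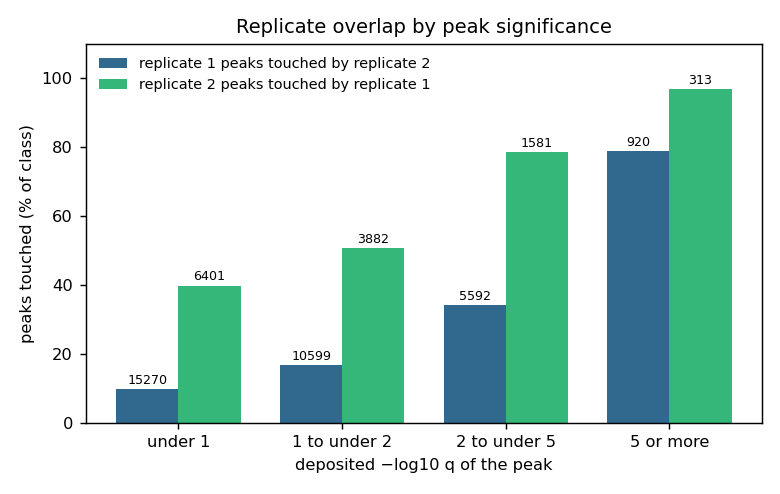
Share of each replicate's peaks touched by a peak of the other replicate's unfiltered list (vertical axis, in %), by the deposited −log10 q of the peak (horizontal axis, 4 classes). The number above a bar is the number of peaks in the class, and the share rises from 9.72% to 78.8% in replicate 1 and from 39.8% to 96.8% in replicate 2.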

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

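The summaries of contig peaks were chosen after the result was seen. Peaks on contigs that are not placed on a chromosome entered no gene or placement test, and 185 replicated peaks (1.36%) lay there. They were counted among the replicated peaks found in each replicate's list and ranked by fold, but had no part in the tests. They were spread over 19 contigs, 46 of them on the contig JH584304, and 18 of the 40 replicated peaks with the highest −log10 q lay on contigs. Their median −log10 q was 9.29, against 3.07 for peaks on assembled chromosomes, while the median folds were 3.53 and 3.24. The replicates' own lists held 253 and 233 such peaks. The assembled regions with the highest −log10 q lay over Sfi1 and Drg1 on chromosome 11 (3190956 to 3195146, −log10 q of 161 at a fold of 4.25) and over Gm26917 and CT010467.1 on chromosome 17 (39843011 to 39846796, 80.4 at a fold of 2.47). No filter for multi-copy sequence was applied here, and its part in these values was not tested.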

How the results depend on the processing

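The settings without zinc finger and protocadherin genes, and with 1 gene per cluster for the gene lists, were chosen after the data were seen. For last exons the setting with 1 gene per cluster was planned. Of 197 alternative values, 147 kept their direction and their side of the threshold or, for the values without a test (chromosome cover, correlation of folds and peaks in both lists), stayed within the limits set for them. Imprinted and zinc finger genes passed in 9 of 9 alternatives each (ratios 2.67 to 20.7 and 2.52 to 11.6), protocadherin genes in 8 of 8 (2.34 to 44.9), germline genes in 8 of 9, and last exons (63.0% to 83.3% of genes), overlap (10% to 30% and 26.7% to 71.2%) and repeat content (22.9% to 27.0%) in all of theirs. Depth is unknown. No paired analysis was possible because there is 1 group. Where a value changed, the cause was not tested unless named.

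With a −log10 q of at least 2, the lists held 6686 and 2037 peaks, and with at least 5, 1031 and 399. Reciprocal overlap of at least 0.5 put 22.1% of replicated peaks in both lists. Promoters moved to ratios of 1.07 (any base), 1.02 (window of 5 kb), 2.04 (−log10 q of at least 5) and 0.869 (without peaks and placements in zinc finger and protocadherin genes), and from 0.974 to 1.17 with each replicate left out. Outside genes the ratio was 0.878 at a −log10 q of at least 5. Exons fell to 0.970 without peaks and placements in zinc finger and protocadherin genes, which held the excess. Where the peaks alone were left out, which lowers ratios within genes by construction, promoters had 0.855 and exons 0.947.

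Vomeronasal genes had ratios of 1.75 (rotations, adjusted permutation p = 0.10; 0.00053 to 1 over its alternatives), 1.11 (Fisher's test), 1.87 (1 gene per cluster, adjusted permutation p = 0.18) and 0.956 (−log10 q of at least 5). Germline genes had 1.34 with at least 1 kb covered. Olfactory genes had 0.191 (at least 1 kb), 1.49 (pooled list, adjusted permutation p = 0.00053; 9.2e-25 to 1 over its alternatives, Fisher's test included), 0.0977 (−log10 q of at least 5) and 0.269 (Fisher's test, which leaves their short spans unmatched).

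Small lists changed direction on a few genes. Near the start site, muscle genes had 0, blood genes 1.65 and pluripotency genes 1.68. With at least 1 kb covered, limb patterning genes had 1.12 and neural genes 1.52. In the pooled list, muscle genes had 0.830 and pluripotency genes 1.37. At a −log10 q of at least 5, P450 genes had 0, neural genes 1.76, pluripotency genes 2.34 and housekeeping genes 1.82. Defensin genes had 1.02 in rotations and P450 genes 0.962 in Fisher's test. Without a change of direction, the pooled list called P450 genes (1.59, adjusted permutation p = 0.039; 0.039 to 1 over their alternatives), and Fisher's test, which leaves spans unmatched, called defensin genes (0.128, adjusted p = 0.014; 0.014 to 1 over their alternatives) and keratin genes (0, adjusted p = 5.3e-06; 5.3e-06 to 1) under-represented.

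With each replicate left out in turn, ratios ran from 2.76 to 4.47 for imprinted, 2.64 to 4.78 for zinc finger, 2.34 to 3.65 for protocadherin, 1.78 to 2.85 for germline, 2.13 to 2.16 for vomeronasal, 0 to 0.710 for defensin, 0 to 0.200 for keratin, 0 to 0.828 for liver, 0 to 0.339 for blood, 0.921 to 1.58 for olfactory, 0.928 to 1.55 for P450, 0.387 to 0.939 for limb patterning, 0.390 to 0.813 for muscle, 0.772 to 1.10 for neural, 0.680 to 1.32 for pluripotency and 0.542 to 1.04 for housekeeping genes. Relative cover ran from 1.96 to 2.04 on chromosome 7, 1.84 to 1.92 on 17 and 0.199 to 0.267 on X.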

Other observations

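The tests of scaling, background and peak significance in the replicates were chosen after the results were seen, as were the search of gene families by symbol and the genes named from it; the tests of the X chromosome, of repeats and of zinc finger product names were written down before their results were seen.

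Gene families outside the 16 lists were searched by the letters that open their symbols. None of 321 families with at least 8 protein-coding members passed after Benjamini-Hochberg adjustment. Lowest in p were secretoglobin genes (Scgb, 5 of 34 members with a replicated peak against 0.622 in span-matched lists, permutation p = 0.0004, adjusted permutation p = 0.13), Ceacam genes (6 of 15 against 0.810, adjusted permutation p = 0.13) and Nlrp genes, which include oocyte and early embryo factors (8 of 17 against 2.43, adjusted permutation p = 0.19). The Nlrp members with a peak, Nlrp2 and Nlrp5 among them, lay in 7 clusters, and those of Scgb in 1. The 9 Ugt genes with a peak all lay in the Ugt1a domain on chromosome 1 (adjusted permutation p = 0.43). All 7 Skint genes with a peak lay in 1 cluster (7 of 11 members, 26.6 kb, adjusted permutation p = 0.58).

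A hypothesis was that zinc finger genes carry the mark as a class, whatever their symbol. By RefSeq product name 434 genes were zinc finger genes, and 347 of them were in the list, so most of the class lay outside this test. The other 87 had a replicated peak in 14 members, against 13.4 in span-matched lists (ratio 1.04, permutation p = 0.96). This argues against the hypothesis for these 87 genes. Of these, Gm4924 (14.9 kb in 21 peaks) and Gm10778 (4.70 kb in 5 peaks) on chromosome 10 and 3300002I08Rik (6.11 kb in 9 peaks) on chromosome 2 had the largest covered shares of their spans. With a ratio of 1.04 outside the list, the excess may belong to part of the zinc finger genes only.

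Replicate 1's list was 2.63 times as long as replicate 2's, and 3 technical explanations were weighed; no biological explanation was tested, since there is 1 group. Under a model in which fold is reads plus 1 over background plus 1 and p is a Poisson tail, 100% of replicate 1's peaks came out of whole reads (to within 0.001 in −log10 p) but 0.306% of replicate 2's; after scaling reads by 0.788, 99.9% of replicate 2's peaks did, so ChIP reads may have been scaled down in replicate 2 alone. In reads of its own library, the commonest background was 3.02 in replicate 2 and 2.6 in replicate 1, which argues under that model against a shallower ChIP library behind the shorter list. After the scaling, the commonest background of replicate 2 was 2.38, below that of replicate 1. Peaks near the threshold that come and go could account for part of the mismatch. The share that touched the other, unfiltered list was at least 2.43 times higher at a −log10 q of 5 or more than under 1. In replicate 1, 725 of 920 such peaks touched it and the others did not. With both lists held to at least 5, 22.7% of these 920 peaks did, against 18.2% of all its peaks without a limit. A stricter limit on both lists thus did not remove the mismatch. How many peaks the scaling cost was not tested.

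The X chromosome's low cover (0.168 of the genome's mean) was not removed by its repeats, since per unmasked Mb it lay at 0.200, against 0.599 for the lowest autosome. Nor was it removed by leaving out genes, such as the zinc finger clusters of other chromosomes: outside genes it lay at 0.124, against 0.560. A lower number of X copies in pools of both sexes stays open. The X held 80 peaks of fold 3 or more (95% exact Poisson interval 63.4 to 99.6), fewer than the 122 that autosomal peaks of fold 4 or more give for a copy number of 0.75, and more than the 8.05 that peaks of fold 6 or more give for 0.5. The interval treats peaks as independent, but 18.1% of replicated peaks lay in domains of 5 or more peaks, so it may be too narrow. These limits also take fold as proportional to copy number, which the model above gives only roughly. The sexes' shares in the pools are not given in the labels, so a low copy number and a low level of the mark on the X cannot be told apart.

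Replicated peaks held fewer repeats than random placements, 26.0% against 33.7%. Their placement in genes and exons does not remove this, since peaks outside genes held 27.4%, against 38.6% ± 0.413 (SD over 100 placements). The 200 bases on either side of peaks held 34.5%, above the 33.7% ± 0.262 beside random placements, so loss of reads in repeats at the edges of peaks may contribute, although that excess is small beside the deficit within peaks. These flanks do not measure reads lost inside repeats, where random placements could fall. The deficit therefore does not show that the mark is low in repeats. No biological explanation was tested.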
